A study of Mus musculus with 23 samples.

How the data were processed

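RNA-seq of whole mouse hippocampus was analysed in 23 libraries: 6 from WT mice in normoxia, 6 from WT mice in hypoxia, 5 from P301S mice in normoxia and 6 from P301S mice in hypoxia. Per the labels, the mice were of a mixed C57Bl6 and Balbc background, RNA came from frozen tissue and passed a quality threshold before sequencing. Libraries were made with a stranded mRNA kit, barcoded and sequenced as paired-end reads in one flow cell. The regimen of hypoxia, the age and sex of the mice, the time of day of collection and the dates of library preparation are not given in the sources used here. Groups were taken from the genotype and condition labels, and replicates were numbered in accession order, so a replicate number only names a library. Titles carry a further number of unexplained meaning that some libraries of a group share. Sharing occurs in WT only, with 66 for WT normoxia replicates 1 to 5. In WT hypoxia, replicates 1 to 4 carry 31 and replicates 5 and 6 carry 32. No number occurs in both conditions, so whatever it stands for cannot be separated from hypoxia in WT.

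Per the file headers, the deposited values are raw counts of read pairs per gene, made by the authors with featureCounts 1.6.2 and the Ensembl release 90 annotation of GRCm38, from alignment files whose names mark duplicates as removed. The submitters' processing notes name HISAT2 as a tool, mm10 as the genome build and DESeq2 1.6.3. Per the command in the file headers, read pairs were counted over whole gene bodies, introns included, with no strand setting although the kit is stranded. Reads that overlap more than 1 gene are dropped by that tool's default, which affects genes that overlap on either strand: 48% of the tested genes overlap another gene in some part and 822 over more than 50% of their length. Removal of duplicates can lower the counts of short abundant transcripts more than those of others. No normalization had been applied to the counts.

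The files hold 52636 Ensembl genes. GENCODE release M21, an annotation of the same assembly, gave symbols for 52403 of them, and the 17788 tested genes all matched. Of the tested genes, 17746 had a GC content. Coordinates are those of the count files, counted from 1. The reference was used for symbols, exon length, GC content and gene type alone. Counts of genes without a symbol made up 0.0427% to 0.101% of a library. Total counts ran from 19.1 to 25.8 M per library, mitochondrial genes took 2.14% to 2.99% and the 10 most abundant genes 3% to 3.67%. Correlations between libraries of a group ran from 0.976 to 0.993. Every such pair differed by more than sampling noise (chi-square per degree of freedom at least 5.04). Separate preparations from 1 animal could differ in this way too, so it does not show separate animals. Each library was counted as 1 replicate. The floor for a group with 0 counts was set at 3 counts over the group, and it covers counting error alone.

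Tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, with tables read by version 1.17.8 of data.table. Genes were kept by filterByExpr with the groups (minimum count 10), which removed 0.0539% to 0.0881% of a library's counts, and libraries were scaled by TMM factors (0.961 to 1.03). One quasi-likelihood model with 4 group means was fitted to all 23 libraries, with robust dispersions, and 5 contrasts were tested two-sided. These were P301S against WT in normoxia and in hypoxia, hypoxia against normoxia in WT and in P301S, and the difference of the hypoxia effects between the genotypes (interaction). Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Standard errors were derived from the fold change and its F statistic. Gene list tests used limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 40 lists with at least 5 measured members of the 42 fixed lists. Each was repeated with an estimated correlation and with fry, which tests whether the members move one way on balance and does not compare them with other genes. The lists cover pathways, cell types and neighbouring brain regions, and 694 of their 748 entries were measured. No list was called in any of the 5 contrasts with an estimated correlation, where the lowest adjusted p was 0.0608.

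Genes named in the text follow a rule fixed before the data were examined. The rule took Mapt and Prnp, up to 10 higher and 10 lower called genes with the largest absolute log2 fold change among those with a mean of at least 1 CPM and a symbol that is not a predicted name, and up to 4 members with the lowest p of each list described. A name outside the rule is said to be chosen after its values were seen. The design, the tests of genes and of gene lists, and the lists were fixed before the data were examined as well. The exact tests of group scores per library were not in that design, so their p-values are not those of planned tests. Group scores per library were compared by exact two-sided permutation tests over all regroupings, and comparisons of all WT with all P301S libraries by 1e+05 resamples.

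The script was tested on simulated counts drawn from the means, dispersions and library sizes of the real data with 200 changed genes among the 17788. The changed genes were taken only from those with higher mean counts, so the recovered shares do not cover genes with few counts. For the normoxia genotype comparison, 41.8% of genes changed 1.25-fold, 80.6% of those changed 1.5-fold and 95.5% of those changed 2-fold were recovered. The shares were 38.8%, 79.1% and 95.5% for hypoxia in WT, 49.3%, 76.1% and 89.4% for hypoxia in P301S, 31.3%, 85.1% and 98.5% for genotype in hypoxia, and 7.46%, 62.7% and 84.8% for the interaction. Of the genes called in these simulations 2.68% to 7.1% were unchanged ones. A simulated list shifted 1.3-fold was called by camera with both correlations and by fry in all 5 contrasts. Each gene was drawn independently of the others, so this does not show how the list tests behave where genes are correlated.

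Alternatives planned before the data were examined were median-ratio (RLE) size factors, no low-count filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom and the legacy quasi-likelihood method. Others were a fit to the compared groups alone, 1 surrogate variable (sva 3.50.0), the choroid plexus score as a covariate, libraries of a group that share a title number as a block, a threshold of 0.1, and each library left out in turn. After the data had been seen, offsets that remove each library's smooth trend with gene-body length and transcript GC content were added, and fits without the 6 libraries whose choroid plexus score lay more than 2 below the mean. These libraries were WT normoxia replicate 4, WT hypoxia replicates 1, 4 and 5, and P301S hypoxia replicates 1 and 4. A covariate for Y-linked genes was not run, as the libraries did not differ in them. Each contrast was also set against 100 other groupings of the same libraries.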

Results

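Hippocampal RNA was sequenced from wild-type (WT) mice and from mice carrying the P301S tau transgene, each kept in normal air (normoxia) or exposed to hypoxia. P301S is a mutation of human tau found in familial frontotemporal dementia, and mice expressing it develop tau tangles and lose neurons. The series title names the exposure as chronic intermittent hypoxia, the repeated loss of oxygen that occurs in sleep apnoea, and asks how it acts on tau pathology and its molecular signature. There were 6 WT normoxia, 6 WT hypoxia, 5 P301S normoxia and 6 P301S hypoxia libraries. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries. Total counts per library ranged from 22.8 to 25.8 M in WT normoxia and 19.1 to 24.9 M in WT hypoxia. They ranged from 23.1 to 25.4 M in P301S normoxia and 23.8 to 25.8 M in P301S hypoxia. In total, 17788 genes passed the filter on low counts and were tested. Fold changes below are log2 values from edgeR with their standard errors (SE), and adjusted p is the Benjamini-Hochberg value of its quasi-likelihood test over all tested genes. Levels are in CPM, counts scaled by library size, as mean ± SD over libraries.

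The genotype labels were first checked against the mouse tau gene and the prion locus. Mapt, the mouse tau gene (chromosome 11, 104231390 to 104332090, GRCm38), was at similar levels in all groups, from 679 ± 52.5 CPM (n = 6) in P301S hypoxia to 713 ± 41.6 CPM (n = 5) in P301S normoxia. The log2 difference between the genotypes was 0.01 (two-sided permutation p = 0.74). The transgene is human tau, and reads from it may or may not be counted at mouse Mapt. Equal Mapt counts therefore do not show whether the transgene was expressed. Prnp, the prion protein gene whose promoter drives several tau transgenes, could not be measured. Of its length, 99.9% lies under the overlapping gene Prn, and it received 2 counts over all 23 libraries. Prn and Lamr1-ps1 at that locus separated the genotypes without overlap, while Prnd, which lies wholly under Prn, had 0 counts over all 23 libraries. Prn (ENSMUSG00000098754, chromosome 2, 131909957 to 131956130) had 0.232 ± 0.102 CPM in WT normoxia (n = 6), 0.357 ± 0.03 in WT hypoxia (n = 6), 3.94 ± 0.675 in P301S normoxia (n = 5) and 4.31 ± 1.18 in P301S hypoxia (n = 6). Lamr1-ps1, a processed pseudogene just upstream (ENSMUSG00000081229, chromosome 2, 131904086 to 131904959), had 0 counts in the 12 WT libraries and 2.98 ± 0.689 CPM in the 11 P301S libraries. Against a floor of 3 counts over the WT libraries together, Lamr1-ps1 was at least 282-fold higher in P301S. The permutation p was 1e-05 for both RNAs, the smallest that 1e+05 resamples give. Prn shares most of its length with Prnp, so its count is uncertain as a measure of Prn alone.

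**Figure D1:**
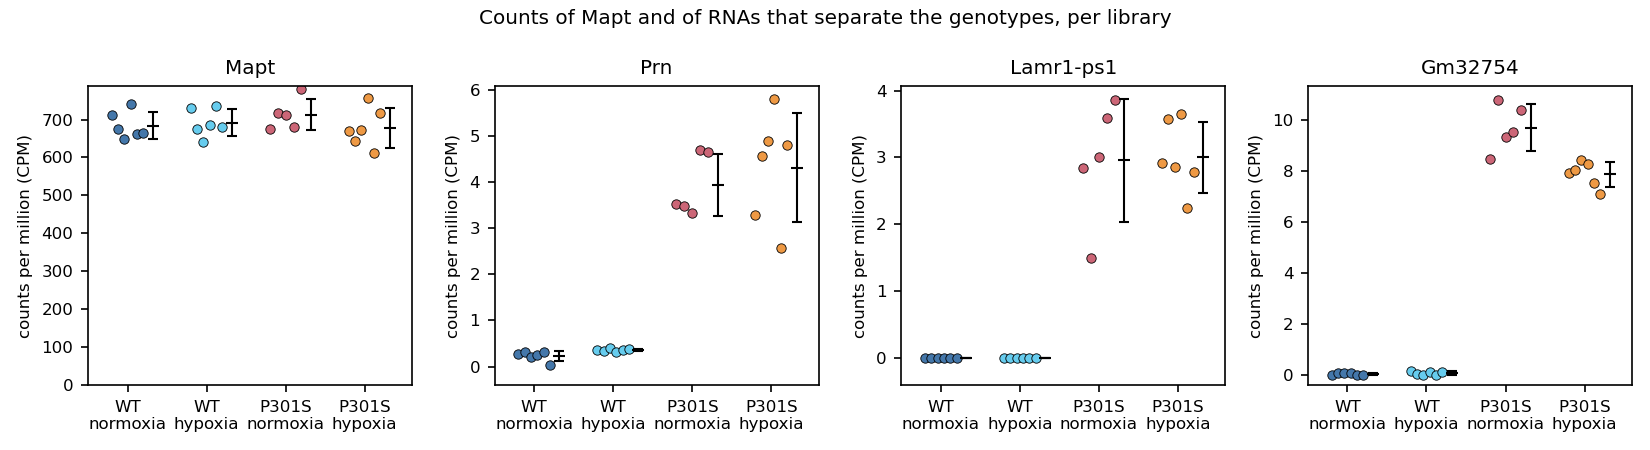
CPM (y axis) of Mapt, Prn, Lamr1-ps1 and Gm32754 in each library (points) of the 4 groups (x axis), with mean and SD as bars. Gm32754, an RNA on chromosome 3, was chosen after its values were seen. Mapt overlaps between the genotypes, while each P301S library lies above each WT library for the other RNAs. Gm32754 has 7.1 to 10.8 CPM in P301S and at most 0.155 in WT.

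In normoxia, P301S hippocampi had lower levels of ribosomal protein, mitochondrial respiration and endoplasmic reticulum (ER) chaperone genes than WT, and higher levels of long genes. Of the 17788 genes, 1130 differed, 458 higher and 672 lower in P301S. Most differences were small, with a median absolute log2 fold change of 0.31 among the called genes. Of the 25 cytosolic ribosomal protein genes, 18 fell and the other 7 did not pass the test, and 20 fell when adjusted over the list alone. Rps14 fell by 0.37 (SE 0.0817, adjusted p = 0.012), from 89.3 ± 7.5 CPM in WT (n = 6) to 69.3 ± 8.79 CPM in P301S (n = 5). Rpl32 fell by 0.31 (SE 0.0701, adjusted p = 0.012) and Rplp0 by 0.31 (SE 0.0697, adjusted p = 0.013). The list was lower than other genes (camera adjusted p = 1.07e-14), with adjusted p = 0.229 with an estimated correlation. Ribosomal protein genes have many near-identical pseudogene copies, so their counts are uncertain.

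Of the 23 measured oxidative phosphorylation genes, 11 fell and none rose, 17 adjusted over the list alone (camera adjusted p = 3.39e-11, and adjusted p = 0.148 with an estimated correlation). The ATP synthase subunit gene Atp5b fell by 0.28 (SE 0.0472, adjusted p = 0.00266) and the complex I gene Ndufb9 by 0.32 (SE 0.0619, adjusted p = 0.00509). Of the 20 ER stress genes, 11 fell and none rose, also when adjusted over the list alone (camera adjusted p = 7.84e-09, and adjusted p = 0.229 with an estimated correlation). Sdf2l1, a partner of ER chaperones, fell by 0.86 (SE 0.164, adjusted p = 0.00509). Xbp1, a transcription factor of the unfolded protein response, fell by 0.44 (SE 0.0839, adjusted p = 0.00509), and the lectin chaperone gene Calr by 0.34 (SE 0.0665, adjusted p = 0.00554). Manf had a change of -0.51 (adjusted p = 0.00569), but 92.3% of it is overlapped by Dcaf1 and its count is uncertain. Among 19 heat shock and chaperone genes, 4 fell, 7 adjusted over the list alone (camera adjusted p = 0.000429, and adjusted p = 0.456 with an estimated correlation). These included the Hsp90 co-chaperones Stip1 (-0.24, SE 0.0519, adjusted p = 0.0104) and Fkbp4 (-0.28, SE 0.0662, adjusted p = 0.015).

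Smaller shifts involved hypoxia-inducible factor (HIF) target, antioxidant and lysosome genes. Of 26 measured HIF targets, 4 fell, 5 adjusted over the list alone (camera adjusted p = 0.0183, and adjusted p = 0.229 with an estimated correlation). The 4 were the glycolytic enzyme genes Ldha (-0.32, adjusted p = 0.0117), Tpi1 (-0.26, adjusted p = 0.0152), Aldoa (-0.27, adjusted p = 0.0254) and Pgk1 (-0.16, adjusted p = 0.0421). Aldoa is 82.2% overlapped by Fam57b, so its count is uncertain. Of 19 measured NRF2 and oxidative stress genes, 3 fell, as when adjusted over the list alone (camera adjusted p = 0.00844, and adjusted p = 0.229 with an estimated correlation). These were Gsta4 (-0.29, adjusted p = 0.0252), Gpx4 (-0.37, adjusted p = 0.0281) and Sod1 (-0.24, adjusted p = 0.0388). Of 23 measured lysosome and autophagy genes, 2 fell, 5 adjusted over the list alone (camera adjusted p = 0.00341, and adjusted p = 0.456 with an estimated correlation). They were the hexosaminidase gene Hexa (-0.19, adjusted p = 0.0292) and the autophagy receptor gene Sqstm1 (-0.19, adjusted p = 0.0385). The 23 measured immediate early genes were lower as a list (camera adjusted p = 0.00574, and adjusted p = 0.75 with an estimated correlation) with no member called. Junb was at -0.36 (adjusted p = 0.0709) and Nptx2 at -0.48 (adjusted p = 0.0776).

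Potassium and calcium channel genes were the list that was higher, with 3 of 24 called and 6 adjusted over the list alone (camera adjusted p = 0.00198, and adjusted p = 0.75 with an estimated correlation). Cacna2d3 rose by 0.27 (SE 0.0508, adjusted p = 0.00509), Kcnd2 by 0.30 (SE 0.0783, adjusted p = 0.0254) and Kcnma1 by 0.21 (SE 0.0603, adjusted p = 0.0409). After removal of each library's trend with gene length and GC content the list was not called (camera adjusted p = 0.38), and Kcnma1 turned to -0.022. Lower genes among those of kinases and phosphatases that act on tau included Mapk3 (-0.27, adjusted p = 0.0069) and Cdk5 (-0.21, adjusted p = 0.049), with no call for the list. Single genes with large changes included the long non-coding RNA Lncpint (1.11, SE 0.245, adjusted p = 0.012). Others were Fhit (0.92, SE 0.162, adjusted p = 0.00311), Il1rapl2 (0.97, SE 0.24, adjusted p = 0.0206), Sgcz (0.96, SE 0.217, adjusted p = 0.0128) and Slc23a4 (1.01, SE 0.195, adjusted p = 0.00511). Among lower genes were C1ql2, a synaptic organiser of dentate granule cells (-0.79, SE 0.171, adjusted p = 0.0115), and Akr1e1 (-0.88, SE 0.254, adjusted p = 0.0444). Il1rapl2, Sgcz, C1ql2 and Akr1e1 lost their calls after removal of the length and GC trend, and Akr1e1 also in 7 of 11 fits with 1 library left out. Cst7, a gene of disease-associated microglia, rose by 1.34 (SE 0.342, adjusted p = 0.0235) at a mean of only 0.418 CPM, while its list was not called. Markers of neocortex and subiculum had a median of 0.24 and GABAergic interneuron markers of -0.11, and neither list was called (camera adjusted p = 0.113 and 0.22, and adjusted p = 0.876 and 0.75 with an estimated correlation).

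The size and direction of the normoxia difference followed gene length. Across genes, which are not independent replicates, the rank correlation of log2 fold change with gene-body length was 0.40. With the genes in 10 bins of gene-body length, the shortest bin had a median log2 fold change of -0.17, with 9 called higher and 174 lower. The longest bin had 0.11, with 191 higher and 0 lower. After removal of each library's trend with gene length and GC content the count of called genes was 423, of which 309 were among the 1130. Without 6 libraries low in choroid plexus markers it was 421, and with the choroid plexus score as a covariate 1195. Leaving out single libraries gave from 365 genes (without P301S normoxia replicate 2) to 2069 (without WT normoxia replicate 1).

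**Figure D2:**
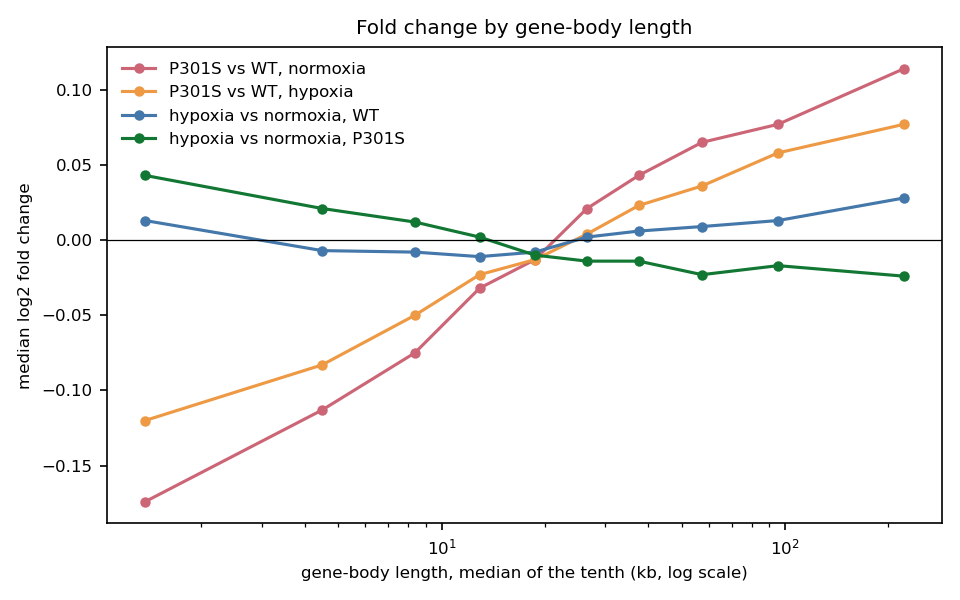
Median log2 fold change (y axis) of the tested genes in 10 bins of gene-body length (x axis, kb, log scale) for the 4 pairwise comparisons (lines). The P301S against WT lines rise with length in both conditions, from -0.17 to 0.11 in normoxia and from -0.12 to 0.08 in hypoxia.

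Hypoxia in WT mice was accompanied by higher levels of the clock output genes Nr1d1 and Dbp and lower levels of activity-regulated genes. Nr1d1, the clock repressor REV-ERB alpha (chromosome 11, 98767932 to 98775333), rose by 0.63 (SE 0.0764, adjusted p = 0.000409), from 70.9 ± 6.05 to 109 ± 12.2 CPM (n = 6 each). Dbp, a clock-driven transcription factor gene (chromosome 7, 45705088 to 45710203), rose by 0.82 (SE 0.11, adjusted p = 0.00102), from 25.1 ± 4.18 to 44.5 ± 6.38 CPM. Fosb, an immediate early gene, fell by 0.71 (SE 0.134, adjusted p = 0.0428), from 10.7 ± 1.95 to 6.57 ± 1.29 CPM. In all, 13 genes differed, 5 higher and 8 lower. Rasal2, a Ras GTPase-activating protein gene, was also higher (0.29, SE 0.0526, adjusted p = 0.0428). So were Nell1 (0.27, SE 0.0524, adjusted p = 0.0428) and Mindy4b-ps (0.97, SE 0.187, adjusted p = 0.0428), which the reference annotates as protein coding. Mindy4b-ps was chosen after its values were seen. Lower genes were Akr1e1 (-1.40, SE 0.252), Arhgef19 (-0.42, SE 0.08), Tjap1 (-0.34, SE 0.0653) and Ccdc30 (-0.33, SE 0.0636), each with adjusted p = 0.0428. The transcription factor gene Atoh8 was lower too (-0.69, SE 0.135, adjusted p = 0.0458). About 14.4% of Dbp and 14.5% of Nr1d1 are overlapped by other genes, where reads were not counted.

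Of the 23 measured immediate early genes in WT, Fosb was called, and 17 fell adjusted over the list alone. Egr2 was at -1.39 (SE 0.282, adjusted p = 0.0627), Homer1 at -0.38 (SE 0.0787, adjusted p = 0.0682) and Nr4a3 at -0.45 (SE 0.0957, adjusted p = 0.0717). The list was lower (camera adjusted p = 2.58e-16), with adjusted p = 0.0608 with an estimated correlation. Of 16 measured circadian clock genes, 2 rose, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.0229, and adjusted p = 0.575 with an estimated correlation). The 18 measured cholesterol synthesis genes were higher as a list, with none called over all genes and 8 adjusted over the list alone (camera adjusted p = 2.06e-07, and adjusted p = 0.166 with an estimated correlation). Stard4 was at 0.34 (adjusted p = 0.0882). ER stress genes were lower, with none called over all genes and, adjusted over the list alone, 12 lower and 1 higher (camera adjusted p = 2.74e-05, and adjusted p = 0.752 with an estimated correlation). Calr was at -0.29 (adjusted p = 0.0824) and Hspa5, the main ER chaperone BiP, at -0.37 (adjusted p = 0.147). The mean log2 CPM of the ER stress list differed by -0.13 between the WT groups (exact two-sided permutation p = 0.0779, adjusted p = 0.162 over 25 such score tests). Heat shock and chaperone genes were lower as a list (camera adjusted p = 0.000779, and adjusted p = 0.752 with an estimated correlation), with Cryab at -0.36 (adjusted p = 0.122).

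Some marker lists of neighbouring tissue and of glial and vascular cells were also called for hypoxia in WT by camera at the preset correlation. In WT, all 15 measured choroid plexus markers and all 13 ependymal markers had negative fold changes, with medians of -0.92 and -0.40 (camera adjusted p = 9.93e-05 and 0.00677, and 0.972 for both with an estimated correlation). Myelin and oligodendrocyte markers were lower (median -0.13, camera adjusted p = 0.0104, and adjusted p = 0.981 with an estimated correlation). Mural cell markers were higher (median 0.27, camera adjusted p = 0.0113, and adjusted p = 0.972 with an estimated correlation), with no member of these lists called. The choroid plexus score, the mean log2 CPM of the markers centred over all libraries, was 0.87 ± 1.87 in WT normoxia and -0.73 ± 2.11 in WT hypoxia (n = 6 each, exact two-sided permutation p = 0.167, adjusted p = 0.273 over 25 such score tests). Without the 6 libraries with the lowest scores no gene was called for hypoxia in WT by edgeR, while 998 genes had an unadjusted p below 0.05. Nr1d1 (0.60, adjusted p = 0.18) and Dbp (0.73, adjusted p = 0.337) lost their calls in that fit alone among 12 alternatives and in 0 of 12 fits with 1 library left out. Nell1 lost its call in 11 of these, Tjap1 in 10, Fosb, Atoh8, Arhgef19 and Ccdc30 in 9, and Rasal2 and Akr1e1 in 8. With the score as a covariate 5 of the 9 list calls of this comparison were kept, and 3 by fry. With 1 library left out, the count ran from 2 (without WT normoxia replicate 4) to 29 (without WT hypoxia replicate 2).

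**Figure D3:**
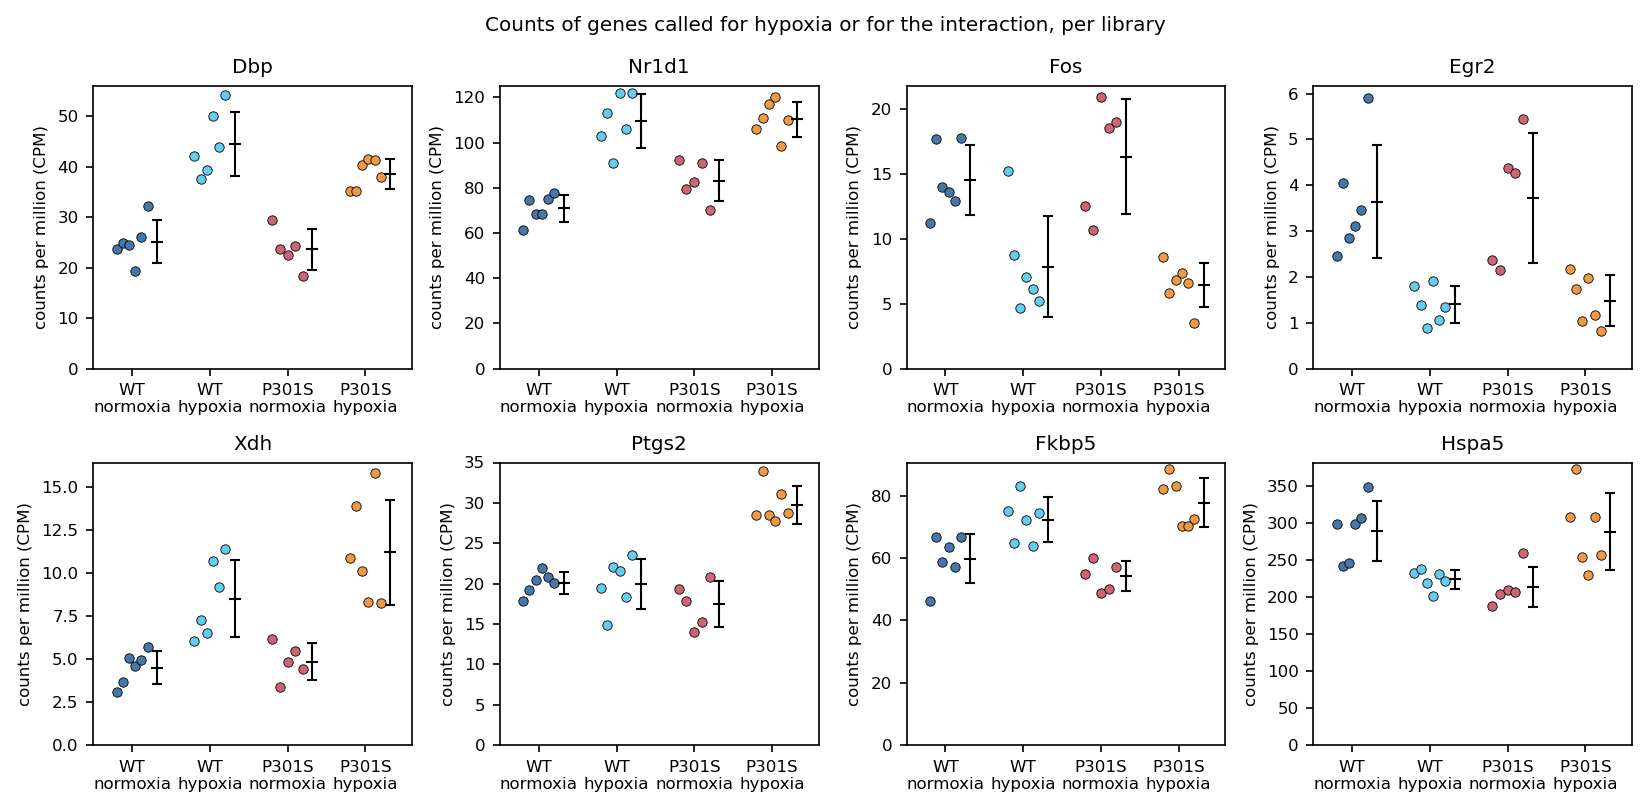
CPM (y axis, starting at 0) of 8 genes called for hypoxia or for the interaction, in each library (points) of the 4 groups (x axis), with mean and SD as bars. Dbp and Nr1d1 are higher in the hypoxia groups of both genotypes, and Ptgs2 reaches 29.8 CPM in P301S hypoxia against 17.4 in P301S normoxia.

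In P301S mice, 73 genes differed between hypoxia and normoxia, 32 higher and 41 lower in hypoxia. Dbp rose by 0.71 (SE 0.117, adjusted p = 0.0109), Nr1d1 by 0.41 (SE 0.08, adjusted p = 0.0272) and Per2 by 0.37 (SE 0.0804, adjusted p = 0.0448), while the 16 measured clock genes were not called as a list. Fos fell by 1.34 (SE 0.249, adjusted p = 0.021), from 16.3 ± 4.47 CPM (n = 5) to 6.44 ± 1.71 CPM (n = 6). In WT, where it was not called, Fos ran from 11.2 to 17.8 CPM in normoxia and from 4.64 to 15.2 CPM in hypoxia. Its interaction was not called. Egr2 fell by 1.34 (SE 0.282, adjusted p = 0.0399), Arc by 0.85 (SE 0.178, adjusted p = 0.0436) and Nr4a1 by 0.57 (SE 0.114, adjusted p = 0.0286). The neurotrophin gene Bdnf, also in the immediate early list, rose by 0.39 (SE 0.0709, adjusted p = 0.0161). Over the 23 measured members 4 fell and 1 rose, and adjusted over the list alone 8 fell and 2 rose (camera adjusted p = 0.0409, and adjusted p = 0.582 with an estimated correlation). The mean log2 CPM of the list differed by -0.20 (exact two-sided permutation p = 0.0476, adjusted p = 0.108 over 25 such score tests).

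Ptgs2, the inducible cyclooxygenase-2 gene (chromosome 1, 150100031 to 150108227), had the lowest p in this comparison and rose by 0.77 (SE 0.102, adjusted p = 0.00158), from 17.4 ± 2.8 CPM (n = 5) to 29.8 ± 2.35 CPM (n = 6). Xdh, the gene of xanthine dehydrogenase, an enzyme of purine breakdown, rose by 1.21 (SE 0.203, adjusted p = 0.0109). In WT, Xdh ran from 3.06 to 5.7 CPM in normoxia and from 6.05 to 11.4 CPM in hypoxia. It was called neither there nor for the interaction, so its rise was not shown to be particular to P301S. Hif3a, a HIF-family gene, rose by 1.67 (SE 0.35, adjusted p = 0.0439), and the glucose transporter gene Slc2a1 by 0.43 (SE 0.0912, adjusted p = 0.0436). The HIF target list as such was not called, with Ldha at 0.17 (adjusted p = 0.289) and Vegfa at -0.14 (adjusted p = 0.315). Of 17 measured glucocorticoid-responsive genes, 1 rose over all genes, and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.000272, and adjusted p = 0.481 with an estimated correlation). Fkbp5, a chaperone gene induced by glucocorticoids, rose by 0.52 (SE 0.0896, adjusted p = 0.0127), with Sgk1 at 0.52 (adjusted p = 0.0525), Zbtb16 at 0.35 (adjusted p = 0.0734) and Dusp1 at -0.52 (adjusted p = 0.0602). Other higher genes were Rtl3 (1.05, SE 0.195, adjusted p = 0.019) and Mfsd2a, a lipid transporter gene of the blood-brain barrier (0.56, SE 0.122, adjusted p = 0.0448). Lfng (0.55, SE 0.0969, adjusted p = 0.0134) and the phagocytic receptor gene Mertk (0.51, SE 0.109, adjusted p = 0.0438) rose too. Other lower genes were Fgf18 (-0.84, SE 0.17, adjusted p = 0.0286) and the potassium channel gene Kcnh4 (-0.57, SE 0.128, adjusted p = 0.0485). Of 11 fits with 1 library left out, Hif3a and Mfsd2a lost their calls in 10, Kcnh4 in 9, Mertk in 8, and Egr2, Arc, Nr4a1 and Fgf18 in 7. Hif3a, Mfsd2a, Mertk and Kcnh4 also lost them with the choroid plexus score as a covariate.

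ER stress genes were higher with hypoxia in P301S, the opposite sign to WT, with none called over all genes and 7 of 20 adjusted over the list alone (camera adjusted p = 1.53e-06, and adjusted p = 0.481 with an estimated correlation). Hspa5 was at 0.44 (adjusted p = 0.0766), Hyou1 at 0.27 (adjusted p = 0.0772) and Sdf2l1 at 0.62 (adjusted p = 0.0989). The mean log2 CPM of the list differed by 0.19 (exact two-sided permutation p = 0.0108, adjusted p = 0.03). Heat shock and chaperone genes were higher too (camera adjusted p = 0.00767, and adjusted p = 0.582 with an estimated correlation), with Hsp90ab1 at 0.17 (adjusted p = 0.0989). Of the neuronal lists, the CA1 and the CA3 and CA2 pyramidal cell markers were not called (camera adjusted p = 0.073 and 0.243), while others were higher. Dentate granule cell markers had 2 of 13 called adjusted over the list alone (median 0.28, camera adjusted p = 2.92e-05, and adjusted p = 0.481 with an estimated correlation). Glutamatergic synapse genes had 1 of 25 (median 0.09, camera adjusted p = 0.00325, and adjusted p = 0.582 with an estimated correlation). GABAergic interneuron markers had 1 of 18 (median 0.08, camera adjusted p = 0.00665, and adjusted p = 0.481 with an estimated correlation). In the last list the neuropeptide Y gene Npy rose by 0.50 (SE 0.0874, adjusted p = 0.0134). Presynaptic vesicle, potassium and calcium channel, oxidative phosphorylation and mitochondrially encoded genes were also higher as lists, with no member called over all genes. Their camera adjusted p was 0.00665, 0.00325, 0.00325 and 0.00665, and adjusted p = 0.582 for each with an estimated correlation.

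Of the lists of glial and non-neuronal cells, 5 were lower in P301S hypoxia, with no member called, while astrocyte, endothelial and mural lists had positive medians and were not called. The lower ones were myelin and oligodendrocyte markers (median -0.17, camera adjusted p = 0.000138), choroid plexus markers (-0.66, 0.0156), ependymal markers (-0.38, 0.0285), meningeal and fibroblast markers (-0.38, 0.00709) and blood cell markers (-0.66, 0.0248). With an estimated correlation the adjusted p of these lists lay between 0.582 and 0.626. Markers of neighbouring brain regions were lower too, with medians of -0.17 for neocortex and subiculum (camera adjusted p = 0.0436) and -0.28 for thalamus and habenula (camera adjusted p = 0.0457), and adjusted p = 0.582 for both with an estimated correlation. The choroid plexus score was 0.56 ± 1.14 in P301S normoxia (n = 5) and -0.60 ± 1.91 in P301S hypoxia (n = 6, exact two-sided permutation p = 0.26, adjusted p = 0.382). Without the 6 choroid-poor libraries 47 genes were called, 28 of them among the 73. Removal of the length and GC trend gave 162, and the choroid plexus score as a covariate 46. With that covariate 11 of the 18 list calls of this comparison were kept, and 0 by fry. With 1 library left out the count ran from 7 (without P301S normoxia replicate 3) to 154 (without P301S normoxia replicate 1). Ptgs2, Xdh and Dbp were called in each of these fits.

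The hypoxia effects of the genotypes, which rest on separate libraries, shared 5 called genes and had 0 called with opposite sign. Rasal2, Dbp and Nr1d1 rose in both, and Gm35552 and 1700016P03Rik, both chosen after their values were seen, fell in both, by 1.05 and 0.96 in WT and by 0.95 and 0.82 in P301S. Independent lists of these lengths would share 0.00899 higher and 0.0184 lower genes. Of the 13 genes called in WT, 12 had the same sign in P301S, and of the 73 called in P301S, 60 had the same sign in WT. Across all tested genes, which are not independent replicates, Pearson's r was 0.08 (jackknife SE over libraries 0.174), Spearman's rho 0.13 and the covariance 0.00504.

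**Figure D4:**
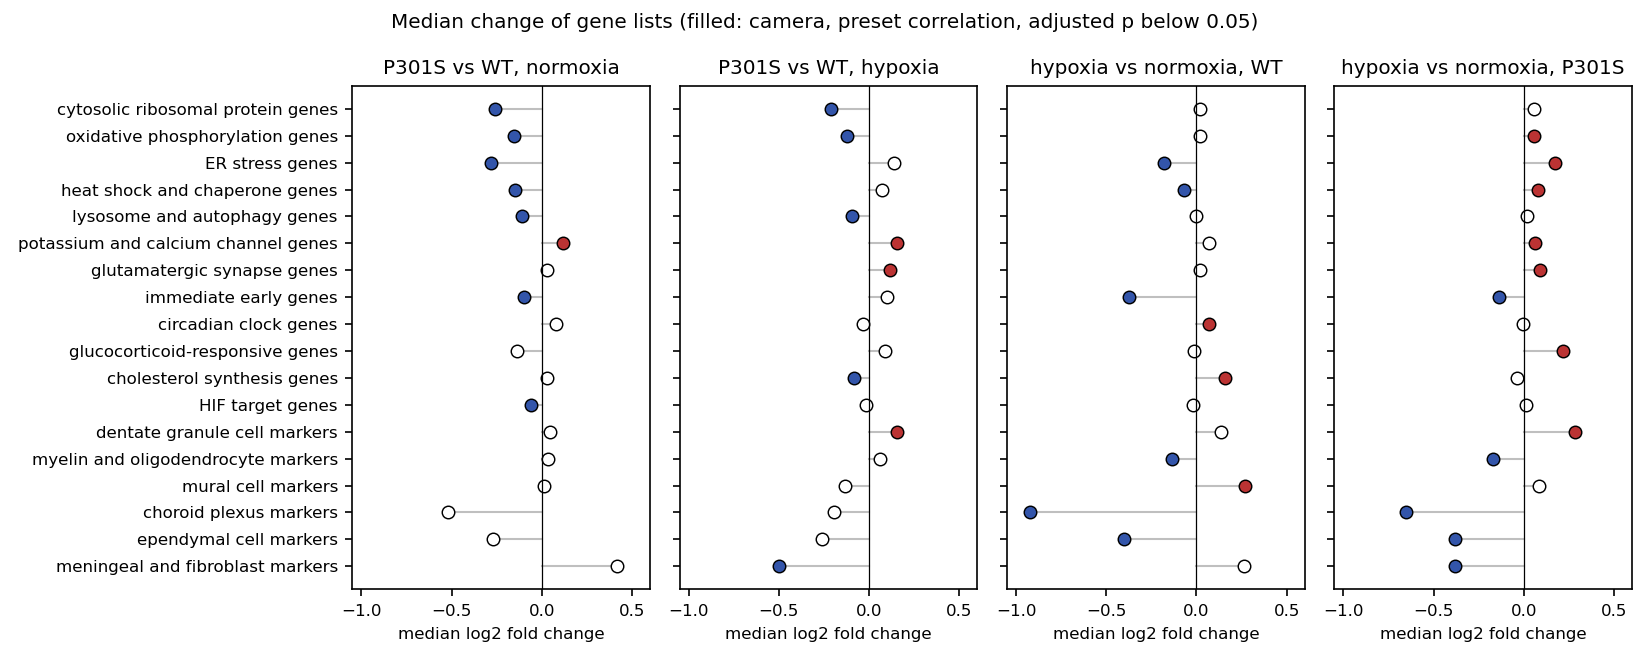
Median log2 fold change (x axis) of 18 gene lists (y axis) in the 4 pairwise comparisons (panels). Filled points, red for higher and blue for lower, passed camera with a preset correlation at adjusted p below 0.05, and none did with an estimated correlation. Ribosomal protein genes are lower in P301S in both conditions, with medians of -0.26 and -0.21, and ER stress genes have medians of opposite sign for hypoxia in WT (-0.18) and P301S (0.18).

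In hypoxia, P301S hippocampi again had lower ribosomal protein and oxidative phosphorylation genes than WT, as lists by camera at the preset correlation. Potassium and calcium channel and glutamatergic synapse genes were higher as lists in the same test, with few members called. A total of 333 genes differed, 94 higher and 239 lower. Of the lower ones 66 were pseudogenes, whose counts are uncertain because they can share reads with their parent genes. Of the 25 ribosomal protein genes 7 fell, 19 adjusted over the list alone (camera adjusted p = 1.15e-16, and adjusted p = 0.264 with an estimated correlation). Rps14 fell by 0.53 (SE 0.0775, adjusted p = 0.000924), Rpl7a by 0.32 (SE 0.0557, adjusted p = 0.0048) and Rps6 by 0.26 (SE 0.0537, adjusted p = 0.0145). Of the 23 measured oxidative phosphorylation genes 4 fell, 8 adjusted over the list alone (camera adjusted p = 1.78e-08, and adjusted p = 0.264 with an estimated correlation). The complex III gene Uqcrc1 was at -0.69 (SE 0.12, adjusted p = 0.00409) and Ndufv2 at -0.25 (SE 0.0453, adjusted p = 0.0066). Of 24 potassium and calcium channel genes 1 rose, 12 adjusted over the list alone (camera adjusted p = 8.39e-08, and adjusted p = 0.331 with an estimated correlation). It was the inward rectifier gene Kcnj6 at 0.35 (SE 0.0923, adjusted p = 0.0475). Of 25 glutamatergic synapse genes 2 rose, 4 adjusted over the list alone (camera adjusted p = 3.01e-05, and adjusted p = 0.331 with an estimated correlation). These were the NMDA receptor gene Grin2a (0.27, SE 0.0651, adjusted p = 0.0299) and the scaffold gene Homer1 (0.30, SE 0.0787, adjusted p = 0.0458).

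Lysosome and autophagy genes were lower as a list, with none of 23 called over all genes and 3 adjusted over the list alone (camera adjusted p = 0.000645, and adjusted p = 0.364 with an estimated correlation). Cholesterol synthesis genes were lower as a list, with 1 of 18 called over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00507, and adjusted p = 0.664 with an estimated correlation). Dentate granule cell markers were higher (median 0.16, camera adjusted p = 0.0237, and adjusted p = 0.788 with an estimated correlation). Meningeal and fibroblast markers were lower (median -0.50, camera adjusted p = 0.0463, and adjusted p = 0.788 with an estimated correlation). Blood cell markers were lower too (median -0.68, camera adjusted p = 0.0463, and adjusted p = 0.687 with an estimated correlation). Among single genes, Akr1e1 was higher by 1.15 (SE 0.255, adjusted p = 0.024) and Ptgs2 by 0.58 (SE 0.0958, adjusted p = 0.00345). Lonrf3 was higher by 0.57 (SE 0.103, adjusted p = 0.00585) and the pyruvate dehydrogenase kinase gene Pdk4 by 0.49 (SE 0.112, adjusted p = 0.025). The neuropeptide gene Cort, made by interneurons, was lower by a log2 value of -0.94 (SE 0.213, adjusted p = 0.0241), and Mapk3, a kinase that acts on tau, by -0.34 (SE 0.0534, adjusted p = 0.00178). The rank correlation of log2 fold change with gene-body length was 0.27. Removal of the length and GC trend left 129 genes, of which 109 were among the 333. The fit without the 6 choroid-poor libraries called 16, with Akr1e1, Ptgs2, Lonrf3, Pdk4, Cort and Uqcrc1 not among them. That fit lacked WT hypoxia replicates 1, 4 and 5 and P301S hypoxia replicates 1 and 4, so it had less power. With the choroid plexus score as a covariate 446 genes were called, including all 333. The score differed by 0.123 between these groups (exact two-sided permutation p = 0.931). With 1 library left out, Pdk4 lost its call in 6 of 12 fits, Cort in 4 and Akr1e1 in 2. Over these fits the count ran from 91 (without WT hypoxia replicate 2) to 618 (without P301S hypoxia replicate 6).

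The genotype effects of the conditions, which share no libraries, had 134 called genes in common with the same sign, 13 higher and 121 lower, and 1 with opposite sign, Akr1e1. Independent lists would share 2.42 higher and 9.03 lower. Of the 1130 genes called in normoxia, 85.9% had the same sign in hypoxia. Across all tested genes Pearson's r was 0.30 and Spearman's rho 0.27.

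The interaction asks whether hypoxia acts differently in P301S than in WT, and it was called for 7 genes, 5 with a positive and 2 with a negative value. The ER chaperone gene Hspa5 (chromosome 2, 34771970 to 34777547) had an interaction of 0.81 (SE 0.15, adjusted p = 0.0435). Its levels were 289 ± 40.4 and 223 ± 13 CPM in WT normoxia and hypoxia (n = 6 each) against 213 ± 27.2 (n = 5) and 288 ± 51.6 CPM (n = 6) in P301S. Calr had 0.53 (SE 0.0917, adjusted p = 0.0407), with 391 ± 29 and 320 ± 14.5 CPM in WT and 309 ± 24.1 and 366 ± 38.3 CPM in P301S. Ptgs2 had 0.78 (SE 0.141), Fam107a, a stress-responsive actin regulator gene, 0.56 (SE 0.0981) and the aldo-keto reductase gene Akr1e1 2.02 (SE 0.36), each with adjusted p = 0.0407. The 2 negative genes, H2-Q2 (-4.42, SE 0.855) and Mybpc2 (-2.30, SE 0.42), both with adjusted p = 0.0407 and both below a mean of 1 CPM, were chosen after their values were seen.

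Of the 20 ER stress genes, 2 were called for the interaction over all genes and 12 adjusted over the list alone, all positive (median 0.35, camera adjusted p = 3.25e-12, and adjusted p = 0.339 with an estimated correlation). Sdf2l1 was at 1.16 (SE 0.225, adjusted p = 0.0618). Heat shock and chaperone genes were positive, 3 of 19 adjusted over the list alone (median 0.15, camera adjusted p = 1.91e-06, and adjusted p = 0.506 with an estimated correlation). So were immediate early genes, 9 of 23 (median 0.28, camera adjusted p = 5.56e-05, and adjusted p = 0.506 with an estimated correlation). Glucocorticoid-responsive genes had 1 of 17 (median 0.24, camera adjusted p = 0.00204, and adjusted p = 0.506 with an estimated correlation). Among immediate early genes Homer1 was at 0.48 (SE 0.114, adjusted p = 0.155). Cholesterol synthesis genes were negative (median -0.16, 3 of 18, camera adjusted p = 0.000207, and adjusted p = 0.506 with an estimated correlation). Glutamatergic synapse genes (0.12, camera adjusted p = 0.0214) and dentate granule cell markers (0.11, 0.0223) had positive medians. Meningeal (-0.92, 0.0026) and thalamic (-0.27, 0.0223) markers had negative ones, and adjusted p = 0.689 held for all 4 with an estimated correlation. No gene was called for the interaction by edgeR after removal of the length and GC trend, without the choroid-poor libraries, with the legacy quasi-likelihood method, or among genes with a mean of at least 1 CPM. In these fits 1873, 1035, 1650 and 1495 genes had an unadjusted p below 0.05, against 1678 with the edgeR settings used throughout, and DESeq2 called 52. Without the choroid-poor libraries the interaction was 0.835 for Hspa5, 0.52 for Calr and 0.78 for Ptgs2. It was 0.42 for Fam107a, 1.675 for Akr1e1, -2.025 for Mybpc2 and -5.245 for H2-Q2. With 1 library left out the count was 0 in 13 of 23 fits (without WT normoxia replicate 1, among others, where 2202 genes had an unadjusted p below 0.05) and at most 13 (without P301S normoxia replicate 1).

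Over the 1130 genes called for genotype in normoxia, signed by their genotype direction, the median hypoxia change was -0.10 in P301S and 0.05 in WT. These comparisons share the normoxia libraries with the genotype comparison, so a value away from 0 arises without any effect. Groups simulated with no effects gave -0.14 and 0.11, and groups simulated with the genotype effect and no hypoxia effect gave -0.06 and 0.04. When the normoxia libraries were split so that separate ones chose the genes and served as the control, the median over 100 splits was -0.06 in P301S, with a range from -0.14 to 0.21 and 83 splits below 0. The observed P301S value lay inside that range. The range is the spread over splits with fewer libraries and no shared ones, not one expected without an effect. It therefore does not decide whether the change differs from 0.

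**Figure D5:**
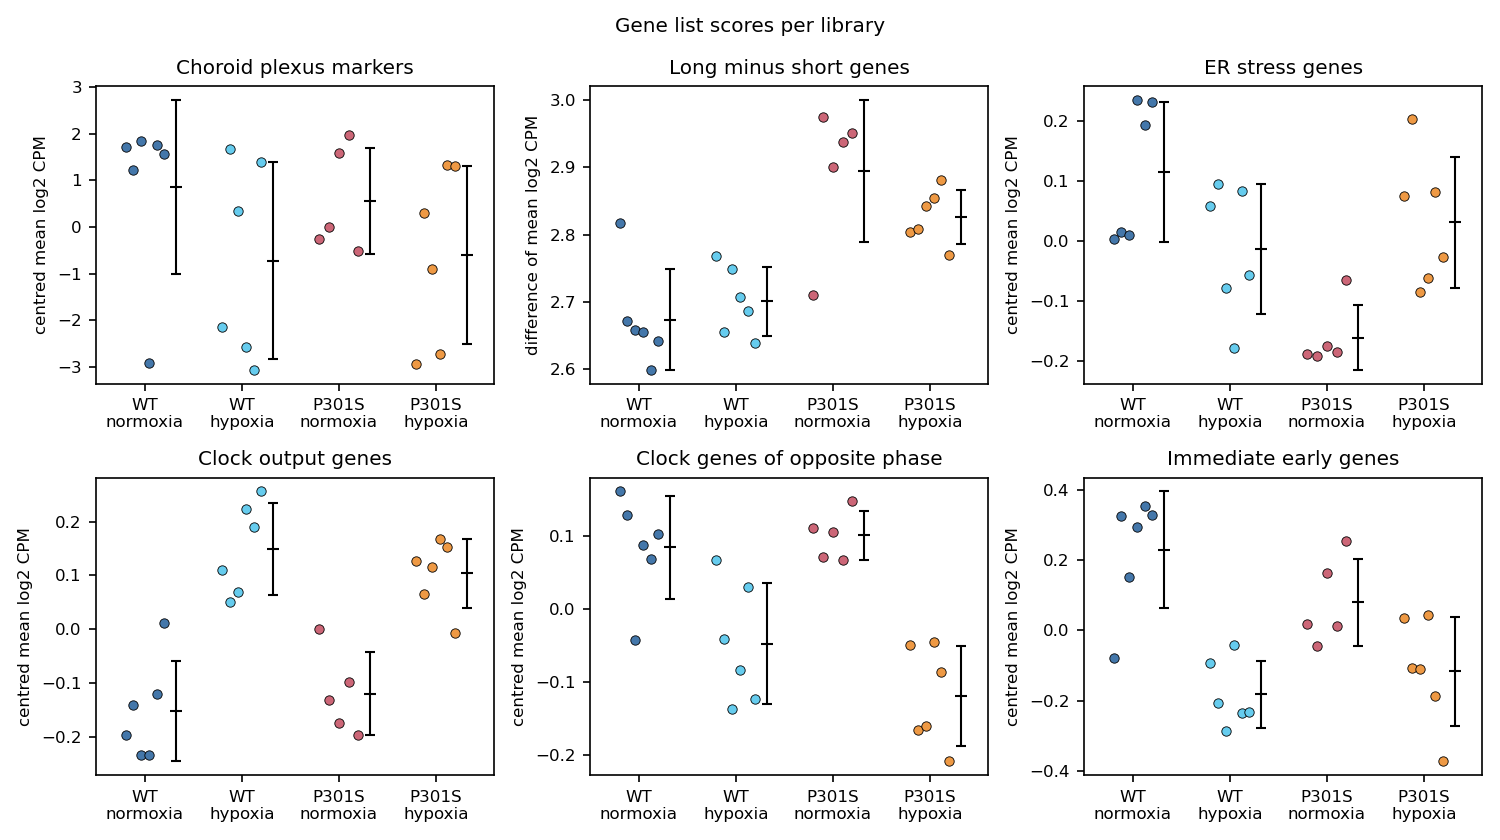
Scores per library (points, with group mean and SD as bars) for 6 measures on log2 CPM scales (y axes) in the 4 groups (x axis): choroid plexus markers, the mean of the longest minus the shortest genes, ER stress genes, clock output genes, clock genes of opposite phase, and immediate early genes. Clock output scores are higher and immediate early scores lower in hypoxia in both genotypes. P301S normoxia replicate 1 lies at 2.71 on the long minus short index, apart from the other P301S normoxia libraries.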

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

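The tests of gene length and GC content and of unspliced RNA were chosen after the results had been seen. So were those of choroid plexus content on the ER genes and of the hypoxia exposure on the clock genes. For the others the prediction was written before the test. The patterns in long and ribosomal protein, ER chaperone, clock and immediate early genes were themselves taken from the results. Their tests were therefore made for patterns already seen.

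P301S libraries in normoxia had higher counts of long genes and lower counts of ribosomal protein genes than WT. Removing each library's trend with gene length and GC content took the ribosomal list's median from -0.26 to -0.15 and left it called (camera adjusted p = 1.74e-08, but adjusted p = 0.229 before the removal with an estimated correlation), which argues against that trend as the whole cause for these genes, although called genes overall dropped from 1130 to 423. More unspliced RNA in the P301S normoxia libraries stays open as a candidate explanation: fold changes followed intron length at equal exon length, GC content and level (partial rank correlation 0.299), and gene-body length more closely in genes with introns (0.387) than in those without (0.244), while between the hypoxia libraries these values were 0.121, 0.274 and 0.279. The P301S genotype stays open too, since 85.9% of the normoxia calls kept their sign between the hypoxia libraries, a share reached by 4 of 100 groupings of those libraries with the real one included (highest other 87.3%). RNA handling and dissection differences that the labels do not record were not tested.

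ER chaperone genes had a positive interaction, being lowest in P301S normoxia (score -0.16 ± 0.0538, n = 5) and highest in WT normoxia (0.12 ± 0.116, n = 6), with WT hypoxia at -0.01 ± 0.109 and P301S hypoxia at 0.03 ± 0.109 (n = 6 each). In WT normoxia, replicates 4 to 6 lay at 0.236, 0.194 and 0.232. Replicates 1 to 3 lay at 0.004, 0.015 and 0.01, inside the WT hypoxia range of -0.178 to 0.095. The list's median interaction was 0.34 with no correction, 0.34 (0.337) with the choroid plexus score as a covariate and 0.39 after removal of the length and GC trend, with the list called each time at the preset correlation (adjusted p = 0.339 with an estimated one and no correction), which argues against both as its cause. A median as large arose in 1 of 100 reshuffles of the condition within genotype, the real one (0.35 by edgeR, largest other -0.30). The ER list had been picked for its interaction in these same libraries, and its median alone was compared with the reshuffles. That choice favours a high rank, so the rank does not decide whether the interaction exceeds what the most extreme list would reach in a reshuffle. An effect of hypoxia that differs between the genotypes may underlie the positive interaction but was not shown by this test. The reshuffles also cannot tell such an effect from an unrecorded difference of the P301S normoxia libraries. Between genotypes the score differed by -0.276 in normoxia (exact permutation p = 0.00216, adjusted p = 0.0108) and by 0.044 in hypoxia (p = 0.506, adjusted p = 0.602). The single-gene calls are weaker: Hspa5 and Calr lost them in 20 and 16 of 23 fits with 1 library left out, and no call was left after the length and GC correction, where Hspa5 went from 0.81 to 0.82 and Calr from 0.53 to 0.51 with adjusted p = 0.073 for both.

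The clock output score was higher with hypoxia in both genotypes, though Per1 (-0.02 in WT, -0.03 in P301S) and in P301S Hlf (-0.04) were not, and immediate early genes lower, by a score that passed in WT (exact adjusted p = 0.018) and did not in P301S (p = 0.0476, adjusted p = 0.108). A difference in the time of day of collection may account for both, since genes of the opposite clock phase (Arntl, Clock, Npas2, Nfil3 and Cry1) had a mean change of -0.18 (permutation p = 9e-05), with -0.13 in WT and -0.22 in P301S, the direction a shift in phase gives. None of the 5 was called in either genotype, and in WT the mean rested on Nfil3 (-0.44) and Arntl (-0.18), with Clock at 0.002 and Npas2 at 0.07. The hypoxia exposure itself cannot be told apart from it, as the labels give no collection times and the change of 0.57 in the clock output score minus the immediate early score only restates the pattern. Choroid plexus content is argued against, as the change of the clock output genes was 0.26 (0.258) with the choroid plexus score as a covariate and 0.27 without, and without the choroid-poor libraries Dbp went from 0.82 to 0.73 and Nr1d1 from 0.63 to 0.60 in WT while losing their calls (adjusted p = 0.337 and 0.18) with fewer libraries.

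Other groupings of the libraries gave as many calls in few cases. For genotype in normoxia, 2 of 100 groupings called as many genes as the real 1130, the real one included, and the highest other called 2099. That grouping set WT normoxia replicates 2, 4, 5 and 6 and P301S normoxia replicate 1 against the other normoxia libraries. It differs from the genotype grouping by 3 of 11 libraries and, as coded, reverses it, with 0.531% of the 1130 genes at the same sign. For the interaction, 2 of 100 reshuffles called as many as the real 7, and the highest other called 105. For hypoxia in WT (real 13, highest other 8), hypoxia in P301S (real 73, highest other 13) and genotype in hypoxia (real 333, highest other 155) the real grouping alone did, 1 of 100 each. Each share lies below 0.05 for a random grouping. For genotype in normoxia and the interaction, another grouping called more genes than the real one. The shares therefore do not exclude that calls follow some other, unrecorded difference between the libraries.

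Single libraries stood apart from their group in 15 of 148 groups of values tested, where about 1 in 20 is reached by chance (7.4 here). WT normoxia replicate 4 lay at -2.92 on the choroid plexus score and at -32.8 on the first principal component (nearest other 9.79), and WT hypoxia replicate 1 at -38.3 on the second component. On the difference between long and short genes, WT normoxia replicate 1 (2.82) lay above its group and P301S normoxia replicate 1 (2.71) below its own. WT normoxia replicate 1 also lay at -0.028 on the score of normoxia genotype genes. Both followed their genotype labels for Lamr1-ps1, which had no counts in WT and at least 35 in each P301S normoxia library. The ER stress score of P301S normoxia replicate 5 was -0.065 (nearest other -0.18). Sdf2l1 was at 6.23 CPM in WT hypoxia replicate 4 and 13.6 CPM in P301S hypoxia replicate 2, and Akr1e1 at 6.03 CPM in P301S normoxia replicate 4. Fam107a was at 462 CPM in P301S hypoxia replicate 1 and Rps14 at 88.6 CPM in P301S hypoxia replicate 6. Among RNAs nearly absent from WT, Gm43049 was at 0.0439 CPM in WT normoxia replicate 2, and 4930590L14Rik at 0.042 CPM in WT hypoxia replicate 6 and 2.1 CPM in P301S hypoxia replicate 3.

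The effect of hypoxia differed between the genotypes, by the interaction term, for 7 genes: Akr1e1 (2.02), Calr (0.53), Fam107a (0.56), H2-Q2 (-4.42), Hspa5 (0.81), Mybpc2 (-2.30) and Ptgs2 (0.78). It differed for 9 lists by camera with a preset correlation. Median interactions were 0.35 for ER stress, 0.15 for heat shock and chaperone, 0.28 for immediate early, -0.16 for cholesterol synthesis, 0.24 for glucocorticoid-responsive and 0.12 for glutamatergic synapse genes. They were -0.92 for meningeal and fibroblast, 0.11 for dentate granule cell and -0.27 for thalamus and habenula markers. With an estimated correlation no list was called, with adjusted p of at least 0.339.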

How the results depend on the processing

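The length and GC correction and the fits without the 6 choroid-poor libraries were chosen after the data were seen, and all other alternatives before. Where a call count moved by more than 1.5 times, the cause was not tested, except that fits without the low-count filter or with fewer libraries or groups adjust over more genes or rest on fewer samples. A threshold of 0.1 gave 2065 genes for genotype in normoxia, 74 for hypoxia in WT, 208 for hypoxia in P301S, 827 for genotype in hypoxia and 15 for the interaction. DESeq2 called 151, 363, 854 and 52 in the last 4 of these. Without the low-count filter the counts were 682, 4, 38, 213 and 4, and with only the compared groups 368, 4 and 182 for genotype in normoxia, hypoxia in WT and genotype in hypoxia. The surrogate variable gave 37, 43 and 16 for hypoxia in WT, hypoxia in P301S and the interaction, and the choroid plexus covariate 46 and 11 for the last 2. The length and GC correction gave 423, 21, 162, 129 and 0, and leaving out the choroid-poor libraries 421, 0, 47, 16 and 0. The interaction had 0 calls with the legacy method and among genes of at least 1 CPM.

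With each library left out in turn, counts ran from 365 to 2069 for genotype in normoxia, 2 to 29 and 7 to 154 for hypoxia in WT and P301S, 91 to 618 for genotype in hypoxia and 0 to 13 for the interaction. The correlation of the hypoxia effects ran from 0.02 to 0.16, the P301S median of the genotype genes from -0.13 to -0.09 and the Mapt difference from -0.005 to 0.03. Of 54 list calls among 200 tests, 0 held with an estimated correlation and 16 with fry. By fry these were 7 of 9 for genotype in normoxia, 3 of 9 and 0 of 18 for hypoxia in WT and P301S, 5 of 9 for genotype in hypoxia and 1 of 9 for the interaction. The choroid plexus covariate kept 5 of 9 and 11 of 18 for hypoxia in WT and P301S, and all in the others. The length and GC correction kept 7 of 9 for each genotype comparison, losing immediate early and channel genes in normoxia (adjusted p = 0.165 and 0.38) and dentate granule and blood cell markers in hypoxia (0.0523 for both). The share of higher genes moved from 40.5% to 26% for genotype in normoxia and from 43.8% to 73.5% for hypoxia in P301S with the length and GC correction. Kcnma1 reversed to -0.022 for genotype in normoxia under that correction. Choroid plexus markers reversed for hypoxia in P301S with the choroid plexus covariate (adjusted p = 0.931), where the covariate is made of the same genes.

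Called in each of 12 alternatives and each left-out fit were Lamr1-ps1, Prn, Slc23a4, Fhit and Sdf2l1 for genotype in normoxia, Xdh, Ptgs2 and Dbp for hypoxia in P301S, and Rpl19-ps11 for genotype in hypoxia, with adjusted p of at most 0.0499. RLE factors ended no call of a named gene or list. No paired analysis was possible because replicate numbers only follow accession order. Libraries that share a title number within a group were treated as a block in limma-voom (duplicate correlation -0.0476), which gave 94 genes for hypoxia in WT and 509 for genotype in hypoxia. Limma-voom without the block gave 10 and 348. As the blocks lie within groups and the correlation was negative, the higher counts show no gain from allowing for a shared source. At this depth the simulations recovered under 50% of genes with the smallest simulated fold change in each comparison.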

Other observations

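The tests of the RNAs on chromosome 3 and of H2-Q2 and Akr1e1 were chosen after their values had been seen, and so were these genes.

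Beside the prion locus on chromosome 2, the RNAs that best separated the genotypes were 3 long non-coding RNAs on chromosome 3 (GRCm38). Gm32754 (140904998 to 140917459) had 15 counts over the 12 WT libraries and 2338 over the 11 P301S libraries, at 8.71 ± 1.17 CPM in P301S. Gm43049 (140692038 to 140760704) had 4 and 772 counts, and 4930590L14Rik (140951876 to 140953247) 1 and 425. Of all genes called for genotype in both conditions with an absolute log2 fold change above 2, these 3 and Prn and Lamr1-ps1 were the only ones. Of these, 5 of 5 lay within 1 Mb of another of them. That count restates the clustering that had been seen and includes the neighbours at the prion locus, so it does not test whether the transgene was inserted on chromosome 3, and the counts hold no reads across a junction.

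Akr1e1 fell with hypoxia in WT, while its log2 value of 0.62 in P301S was not called (adjusted p = 0.281) and its interaction lost the call in 19 of 23 fits with 1 library left out. Its levels were 22.2 ± 6.42 CPM in WT normoxia, 8.4 ± 2.94 in WT hypoxia (n = 6 each), 12.2 ± 3.5 in P301S normoxia (n = 5) and 18.7 ± 5.04 in P301S hypoxia (n = 6). Since the mice were of mixed background, a block of background alleles spread unevenly over the groups could give such a pattern. Where it also varied within groups, neighbouring genes would follow it. Of 12 tested neighbours of Akr1e1 within 2 Mb, 0 did at an absolute correlation of at least 0.6. The same held for 39.5% of all tested genes, and with so few neighbours it does not decide the question. Of 142 neighbours of H2-Q2, 1 followed it (percentile 39.5). H2-Q2 had a mean of 0.258 CPM, too few counts for such a correlation to decide. An allele that acts on Akr1e1 alone was not tested.

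Disease-associated microglia and reactive astrocyte genes, which tau pathology can raise, were not called as lists for genotype in either condition. Nor were homeostatic microglia and general astrocyte markers. Cst7, a gene of disease-associated microglia with a mean of 0.418 CPM, was higher in P301S in normoxia (1.34, SE 0.342, edgeR adjusted p = 0.0235). Its interaction with hypoxia was -1.68 (adjusted p = 0.274). Apoe was at -0.27 for genotype in normoxia (adjusted p = 0.0832). Among 13 mitochondrially encoded genes in hypoxia, mt-Co2 was lower in P301S (-0.34, adjusted p = 0.0169) while mt-Nd4 (0.22, adjusted p = 0.0482) and mt-Nd1 (0.21, adjusted p = 0.0497) were higher, with no call for the list.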
